A study of Mus musculus with 82 samples.

How the data were processed

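RNA of mouse embryonic fibroblasts (23 arrays) and primary hepatocytes (59 arrays), all C57BL/6, was measured on Affymetrix mouse whole-genome arrays. The authors processed the arrays with RMA and Partek, whose versions are not given, and the deposited values are log2 intensities per probe set. Per the labels the authors left out 1 array per cell type as an outlier, technical replicate 1 of WT MEFs with 991 and technical replicate 4 of preparation 1 of dKO hepatocytes with vehicle. All 82 remaining arrays were used. Array medians lay between 6.158 and 6.246 in MEFs and between 5.877 and 6.078 in hepatocytes, and correlations with the rest of the group were 0.9974 to 0.9992 and 0.9966 to 0.9992. No pair of arrays was identical. Because the cell types had different distributions of values, and whether they were normalized together is not given in the sources used here, every test was run within a cell type.

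Of 45101 probe sets, 64 control probe sets were left out. Of the other 45037, 34945 had 1 gene symbol, 932 had several and 9160 had none in the annotation used, and 34741 matched a table of mouse genes by Entrez identifier. These represent 18193 genes, of which 9010 have more than 1 probe set, and the probe set with the highest mean in the cell type stands for the gene. No filter on dim genes was applied.

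Groups, comparisons, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from the settings and tests named as chosen later. The comparisons were each compound against vehicle within each genotype, the interaction (the effect in WT minus that in dKO), 991 against AICAR in WT, and dKO against WT with vehicle. Named genes are Prkaa1 and Prkaa2 (in comparisons with the knockout) and Flcn, the 8 largest rises and 8 largest falls among called genes above the median level with the same sign in every replicate, and up to 4 called members with the largest change in each passing list. Predicted genes, Xist and Y-linked genes could not enter by size of change.

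Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method over all 18193 genes. A gene is called at an adjusted p under 0.05 with no fold limit. In MEFs the model had a mean for each of the 6 groups with 17 residual degrees of freedom, and each array was a sample. In hepatocytes technical replicates were averaged to 12 preparation means, and the preparation within genotype was a fixed block, which left 4 degrees of freedom. The comparison of dKO with WT hepatocytes used 4 vehicle means with 2 degrees of freedom. Python 3.11.15 with pandas 2.3.3 prepared the tables and matplotlib 3.10.9 drew the figures.

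The 29 gene lists cover AMPK subunits and upstream kinases, TFEB/TFE3 lysosome and autophagy targets, cholesterol synthesis and uptake, fatty acid synthesis, gluconeogenesis, glycolysis, fatty acid oxidation and PPAR alpha targets, mitochondrial respiration and biogenesis, the integrated stress response, the unfolded protein response, p53 targets, the NRF2 response, immediate early genes, cell cycle, circadian clock, inflammatory genes, interferon response, purine synthesis, hypoxia, YAP and SRF targets, aryl hydrocarbon and xenobiotic receptor targets, bile acid genes and ribosome biogenesis. The last 6 hold cell type markers, for hepatocytes, fibroblast and stellate matrix, Kupffer cells, endothelium, cholangiocytes and epithelium, and lymphocytes and erythroid cells. They were written from general knowledge, some genes are in more than 1 list, and the tests use their measured members. Each list with at least 5 measured genes was tested with camera at a preset correlation of 0.01, with p adjusted over the 29 lists of a comparison, and again with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. The calls that hold with an estimated correlation are the 15 given with such a p under 0.05 in the Results. Counts adjusted over the list alone correct each gene's p over the members of that list.

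AMPK-dependent means called in WT and in the interaction in the same direction. Expected overlaps assume independent calls. Since both compounds share vehicle arrays, correlations were also computed on 20 simulations without any effect, and overlaps and correlations with the vehicle arrays split between the compounds.

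Alternatives were quantile normalization within the cell type, only genes at or above the median level, the mean of all probe sets of a gene, no trend of the prior variance, a block by technical replicate number in MEFs, no preparation block in hepatocytes, every hepatocyte array as a sample, each preparation alone, and leaving out each MEF array or hepatocyte preparation. Technical replicate numbers did not pair arrays across groups (median r = 0.013 in MEFs and 0.01 in hepatocytes, across genes, after removing group means). Preparation numbers did so within a genotype (median r = 0.699) but ran opposite across genotypes (median r = -0.841), so a crossed block was added for dKO against WT after the data were seen, as was the interquartile range of each MEF array as a covariate. With 2 preparations per genotype 1 of the 2 pairings must correlate positively, and taking that one shrinks the residual, so the crossed block supports no call.

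The code was tested on simulated data of the real design. Of 100 genes changed 1.5-fold and 100 changed 2-fold, 99 and 100 were recovered for 991 in WT MEFs (13 unchanged genes called), 82 and 100 for the MEF interaction (11), 99 and 100 for 991 in WT hepatocytes (7), 96 and 99 for the hepatocyte interaction (10), and 87 and 100 for dKO against WT hepatocytes (27). The shifted list always passed and at most 1 of 28 others did. How correlated lists fare stays open.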

Results

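Gene expression was measured on Affymetrix mouse whole-genome arrays in mouse embryonic fibroblasts (MEFs) and primary mouse hepatocytes. The cells were either control (WT) or lacked both catalytic subunits of AMP-activated protein kinase, AMPKα1 and AMPKα2 (dKO). They were exposed for 4 h to vehicle (DMSO) or to an AMPK activator, 991 or AICAR. MEFs received 991 at 10 µM and AICAR at 2 mM, and hepatocytes received 991 at 3 µM and AICAR at 300 µM, so doses differed between the cell types and between the compounds. The 23 MEF arrays formed 6 groups, with 3 arrays of WT cells with 991 and 4 in each other group. All are technical replicates per the labels, so p-values in MEFs measure technical spread only and not the spread between embryos or cell lines. The 59 hepatocyte arrays came from 2 preparations per genotype with 5 technical replicates per treatment, except 4 for vehicle in preparation 1 of the dKO cells. Technical replicates were averaged, so n = 2 preparations in every hepatocyte group. The number of arrays and preparations limits the precision. The series was made to find which expression changes after AMPK activators need AMPK. Changes below are log2 differences ± standard error (SE), and levels are log2 intensities ± standard deviation (SD). Genes are called at an adjusted p under 0.05 over 18193 genes. A list of genes passes when its members move together relative to the other genes, and the share of lists that still pass with an estimated correlation between genes is small (15 of 143 calls), so that p is given beside each list.

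The comparison of dKO with WT MEFs under vehicle describes the cells before treatment. Prkaa1, which encodes AMPKα1, did not differ between the genotypes on its single probe set (8.26 ± 0.08 in dKO, 8.35 ± 0.13 in WT, n = 4 each, adjusted p = 0.514). Prkaa2, which encodes AMPKα2, was lower in dKO by -0.32 ± 0.08 (5.89 ± 0.1 against 6.21 ± 0.13, adjusted p = 0.00116). The sources used here do not say which part of either gene was deleted, and a probe set outside the deleted part checks nothing. The genotypes differed far beyond AMPK: 8597 genes were called, 5103 higher and 3494 lower in dKO, of which 1412 and 747 differed by at least 1.5-fold. Among the largest differences, Lrp2, an endocytic receptor, was higher by 5.81 ± 0.12 and the homeobox gene Hoxb9 by 4.32 ± 0.14, with Ildr2 (4.58 ± 0.06), creatine kinase B (Ckb, 3.86 ± 0.05) and the interferon-inducible gene Ifi202b (5.43 ± 0.11). The lysosomal protease gene Ctsz was lower by -6.19 ± 0.09, as were the limb patterning genes Lhx9 (-5.78 ± 0.14) and Hoxd13 (-5.49 ± 0.13) and the Wnt pathway genes Rspo2 (-5.76 ± 0.11) and Sfrp2 (-5.32 ± 0.08). Xist, the RNA that coats the inactive X chromosome, stood at 12.75 ± 0.04 in WT and 6.36 ± 0.29 in dKO, and the 4 arrays of each genotype are technical replicates with no separate lines named in the labels, so genotype cannot be separated from the line.

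Fibroblast matrix genes were the list with the lowest camera p between the MEF genotypes. Of 17 measured genes of extracellular matrix, 11 were lower and none higher in dKO (11 lower adjusted over the list alone), among them Col1a2 (-4.68 ± 0.07), the collagen cross-linking enzyme Loxl1 (-3.49 ± 0.05), Postn (-2.33 ± 0.14) and Col3a1 (-2.25 ± 0.07). The matrix list passed at adjusted p = 7.96e-07, and at 0.0148 with an estimated correlation. Targets of YAP and SRF were lower in 12 of 16 and higher in 4, with the same counts adjusted over the list alone, including the smooth muscle gene Tagln (-4.16 ± 0.05) and Thbs1 (-1.32 ± 0.04), against Ankrd1 (0.89 ± 0.04). That list had adjusted p = 0.00369, and 0.262 with an estimated correlation. Hypoxia genes were lower in 10 of 15 and higher in 4 (5 over the list alone), led by Adm (-1.76 ± 0.09). The list had adjusted p = 0.0145, and adjusted p = 0.262 with an estimated correlation. The integrated stress response list, genes driven by ATF4, was higher in 18 of 24 (Chac1 0.79 ± 0.08, Ppp1r15a 0.69 ± 0.04). As a list they passed at adjusted p = 0.000173, and adjusted p = 0.12 with an estimated correlation. Cholesterol synthesis genes were higher in 12 of 20 and lower in 1 (Tm7sf2 1.05 ± 0.05, Hsd17b7 0.66 ± 0.03). This gave adjusted p = 0.00275, and adjusted p = 0.262 with an estimated correlation. Genes of fatty acid oxidation and PPAR alpha were higher in 10 of 18 and lower in 1 (the lipid droplet gene Plin2 1.65 ± 0.03, Pdk4 1.44 ± 0.05, Cpt1a 1.05 ± 0.06). That list had an adjusted p of 0.032, and adjusted p = 0.262 with an estimated correlation, and it no longer passed with the mean of all probe sets of a gene (adjusted p = 0.294).

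Treatment with 991 in WT MEFs asks what a direct AMPK activator changes, and the same treatment in dKO MEFs asks what remains without AMPK. Flcn, which encodes folliculin, a regulator of lysosomal signalling, rose by 0.71 ± 0.07 in WT (9.92 ± 0.2, n = 3, against 9.21 ± 0.09, n = 4, adjusted p = 2.59e-08). Its partners Fnip1 (0.85 ± 0.12) and Fnip2 (0.71 ± 0.06) and the lysosomal sialidase Neu1 (0.80 ± 0.08) rose as well. The largest rise was that of Crebrf, a regulator of a stress-responsive transcription factor (1.09 ± 0.07, adjusted p = 1.35e-12). Large rises were also called for the stress gene Ddit3 (0.79 ± 0.06), the clock repressor Bhlhe40 (0.77 ± 0.05), the acetyl-CoA synthetase Acss2 (0.76 ± 0.09), Rdh11 (0.74 ± 0.08) and the thioredoxin-binding gene Txnip (0.73 ± 0.08). The phosphodiesterase gene Pde4b fell by 0.75 ± 0.08 (adjusted p = 1.22e-07), the transcription factor gene Klf2 by 0.51 ± 0.06 and the chemokine gene Cxcl1 by 0.47 ± 0.08. Smaller falls were those of Il17re (-0.44 ± 0.07), Dido1 (-0.44 ± 0.07), Dbh (-0.44 ± 0.1), Slc1a3 (-0.44 ± 0.1) and Clmn (-0.43 ± 0.1). Most calls were small: of 3582 called genes, 2555 higher and 1027 lower, only 41 and 6 changed by at least 1.5-fold.

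**Figure D1:**
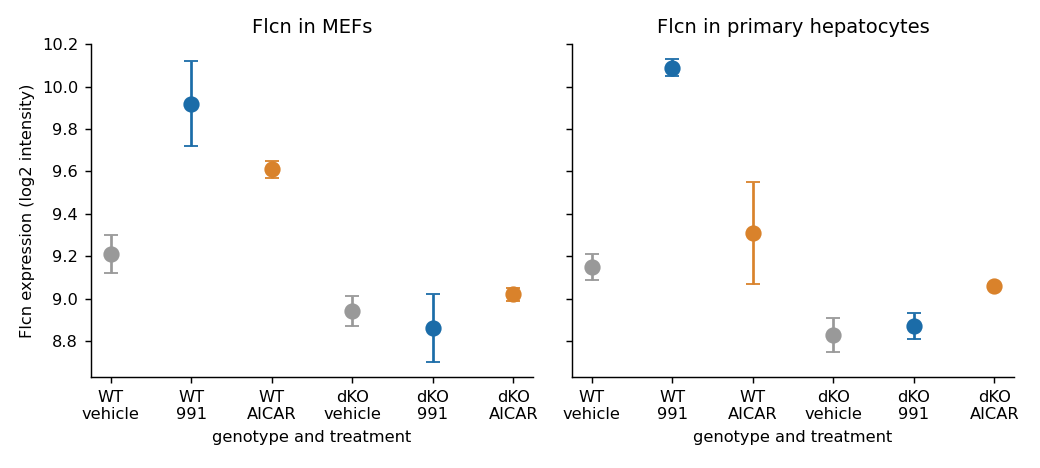
Flcn expression (log2 intensity, vertical axis) by genotype and treatment (horizontal axis) in MEFs and primary hepatocytes; points are means and bars SD over arrays in MEFs (n = 3 or 4) and over preparation means in hepatocytes (n = 2). With 991 in WT cells the level was 9.92 in MEFs and 10.09 in hepatocytes, against 8.86 and 8.87 in dKO cells.

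Lysosome and autophagy targets of TFEB and TFE3 rose in 29 of 38, fell in 1 and were not called in 8 with 991 in WT MEFs, and 30 rose and 2 fell adjusted over the list alone. The median change was 0.20, with an adjusted p of 4.98e-18 for the list and 0.00574 with an estimated correlation. Cholesterol synthesis and uptake genes, targets of SREBP2, rose in 19 of 20 (20 over the list alone), with a median of 0.40: Hsd17b7 (0.69 ± 0.03), Hmgcs1 (0.62 ± 0.04), Lss (0.62 ± 0.05) and Mvd (0.60 ± 0.05) led, and the list passed at 4.07e-31, and at 7.95e-05 with an estimated correlation. The other lists did not pass with an estimated correlation. Fatty acid synthesis genes rose in 9 of 18 and fell in 2 (10 and 2 over the list alone), with Acss2 up and the carbohydrate-responsive regulator Mlxipl lower at -0.31 ± 0.11 (adjusted p = 0.0146, and 0.237 with an estimated correlation). Mitochondrial genes rose in 5 of 23 and fell in 1, the same adjusted over the list alone, led by Ppargc1b at 0.35 ± 0.07 (adjusted p = 0.0146, and 0.237 with an estimated correlation).

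6 further lists passed for 991 in WT MEFs, and all 6 missed the threshold after quantile normalization. Stress response genes of ATF4 rose in 8 of 24 (9 up and 1 down over the list alone), such as Vldlr (0.50 ± 0.07) and Atf3 (0.42 ± 0.09). The list test gave adjusted p = 0.0168, and 0.272 with an estimated correlation. Clock genes rose in 5 of 16 and fell in 2 (7 and 3 over the list alone), such as Dbp (0.62 ± 0.09) and Cry1 (0.38 ± 0.07). Together they had adjusted p = 0.0368, and 0.211 with an estimated correlation. Hypoxia genes rose in 6 of 15, the same over the list alone, such as Ndrg1 (0.61 ± 0.06). For the list, adjusted p was 0.0162, and 0.272 with an estimated correlation. YAP and SRF targets rose in 6 of 16 (7 up and 1 down over the list alone), such as the tissue factor gene F3 (0.43 ± 0.08). Camera gave adjusted p = 0.034, and 0.361 with an estimated correlation. Antioxidant genes of NRF2 rose in 3 of 17 (5 over the list alone), led by Hmox1 (0.37 ± 0.05). They passed at adjusted p = 0.0491, and 0.338 with an estimated correlation. None of 13 bile acid genes was called, and the list was lower with a median of -0.18 (adjusted p = 0.0273, and 0.338 with an estimated correlation). Without WT vehicle replicate 2 the number of 991 calls was 4802, and without WT 991 replicate 2 it was 1889. After quantile normalization 2322 genes were called, of which 1276 were higher (55%, against 71.3% in the values as deposited). With the width of each array as a covariate, a setting chosen after seeing the data, 1101 were called, without Dbh, Slc1a3 and Clmn.

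In dKO MEFs, Prkaa1 (0.02 ± 0.1, adjusted p = 0.953) and Prkaa2 (0.12 ± 0.08, adjusted p = 0.492) did not change with 991. Flcn did not change either (-0.08 ± 0.07, 8.86 ± 0.16 against 8.94 ± 0.07, n = 4 each, adjusted p = 0.614). Among 629 calls (302 to 539 without 1 array), 342 higher and 287 lower, none reached 1.5-fold. Of these, 226 were shared with WT in the same direction and 28 in opposite directions, against 64.2 and 59.6 for independent calls. After quantile normalization 817 were called, 340 higher (41.6%, against 54.4% as deposited). The homeobox gene Prrx1 fell by 0.41 ± 0.04 (adjusted p = 4.75e-07), the cytoskeletal adaptor Sorbs2 by 0.39 ± 0.05 and the activin antagonist Fst by 0.39 ± 0.09, and the DNA repair gene Mpg rose by 0.42 ± 0.11. Inflammatory genes fell in 6 of 20 and none rose (7 fell over the list alone), including Il6 (-0.37 ± 0.1), Ccl7 (-0.35 ± 0.06) and Ptgs2 (-0.28 ± 0.07). The list had adjusted p = 1.05e-05 and 0.00137 with an estimated correlation. Cholesterol genes were higher as a list by a median of 0.08, with 2 of 20 called (10 over the list alone; Nsdhl 0.18 ± 0.03), and adjusted p = 7.43e-06, and 0.124 with an estimated correlation. Immediate early genes, the first to respond to stimulation, fell in 4 of 20 and rose in 2 (6 and 3 over the list alone; Fosl1 -0.24 ± 0.03, Egr1 0.23 ± 0.05). As a list they passed at adjusted p = 0.015, and 0.576 with an estimated correlation. Ribosome biogenesis genes fell in 3 of 20 (5 over the list alone; Nop2 -0.17 ± 0.04). Adjusted p was 8.25e-05, and 0.693 with an estimated correlation. YAP and SRF targets fell in 1 of 16 (Thbs1 -0.22 ± 0.04). This gave adjusted p = 0.0293, and 0.739 with an estimated correlation.

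The interaction was the 991 effect in WT minus that in dKO. Prkaa1 (-0.07 ± 0.15, adjusted p = 0.805) and Prkaa2 (-0.26 ± 0.12, adjusted p = 0.195) showed none, whereas Flcn differed by 0.79 ± 0.1 (adjusted p = 4.44e-06). Crebrf (1.06 ± 0.09), Bhlhe40 (0.83 ± 0.07), Fnip1 (0.83 ± 0.17), the fatty acid transporter Slc27a1 (0.79 ± 0.12), Ddit3 (0.73 ± 0.08), Txnip (0.73 ± 0.11) and Neu1 (0.73 ± 0.11) had larger effects in WT. Pde4b (-0.70 ± 0.11) and Klf2 (-0.67 ± 0.09) were lower for WT minus dKO. There were 961 calls, 795 higher and 166 lower (746 after quantile normalization, 513 higher, or 68.8% against 82.7%). Of 3582 WT calls, 768 (21.44%) were also called in the interaction in the same direction, and are named AMPK-dependent. They may keep an effect in dKO, and other WT calls stay undecided. Among the 47 with a 1.5-fold change, 42 were AMPK-dependent. Over those 47 genes the slope of the dKO change on the WT change was 0.108, where a slope of 1 means equal effects and the choice of genes by their WT change lowers the slope.

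Cholesterol genes had a larger 991 effect in WT than in dKO MEFs in 14 of 20 (18 over the list alone; Hsd17b7 0.59 ± 0.05, Hmgcs1 0.50 ± 0.05). The list test gave adjusted p = 9.78e-25, and 0.000333 with an estimated correlation. TFEB and TFE3 targets did so in 19 of 38 (23 over the list alone). Adjusted p was 1.77e-16, and 0.0088 with an estimated correlation. Clock genes did so in 3 of 16 (5 over the list alone; Dbp 0.62 ± 0.12). Together they had adjusted p = 0.00551, and 0.0359 with an estimated correlation. Lists that passed only with the preset correlation included YAP and SRF targets (5 of 16 higher, 6 over the list alone; adjusted p = 0.000295, and 0.201 with an estimated correlation) and interferon response genes (4 of 17 higher, the same over the list alone; adjusted p = 0.0357, and 0.213 with an estimated correlation). Among the interferon genes, the antiviral Ifit1 (0.78 ± 0.13) and Ifit2 (0.63 ± 0.07) and the signal transducer Stat2 (0.58 ± 0.12) differed. Fatty acid synthesis genes were higher in 5 of 18 (5 up and 2 down over the list alone; Fasn 0.29 ± 0.05), ATF4 targets in 2 of 24 (5 over the list alone), mitochondrial genes in 1 of 23 (Ppargc1b 0.49 ± 0.1) and hypoxia genes in 2 of 15 (4 over the list alone). Each of these 4 lists had adjusted p = 0.262 with an estimated correlation. Ribosome biogenesis genes passed as higher with a median of 0.08 (adjusted p = 0.0367, and 0.46 with an estimated correlation), while their only called member, Nop58, was lower (-0.14 ± 0.04). Marker lists of hepatocyte secreted proteins (14 genes) and of lymphocytes and erythroid cells (12 genes) passed as lower with no member called (adjusted p = 0.0367 each, and 0.363 each with an estimated correlation). Both marker lists, and those of ATF4, hypoxia and ribosome biogenesis, missed the threshold after quantile normalization. Leaving out WT 991 replicate 2 gave 501 interaction calls and leaving out WT vehicle replicate 2 gave 1712. With array width as a covariate, chosen after seeing the data, 382 genes were called, without Fnip1, and 304 of them were among the 961.

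**Figure D2:**
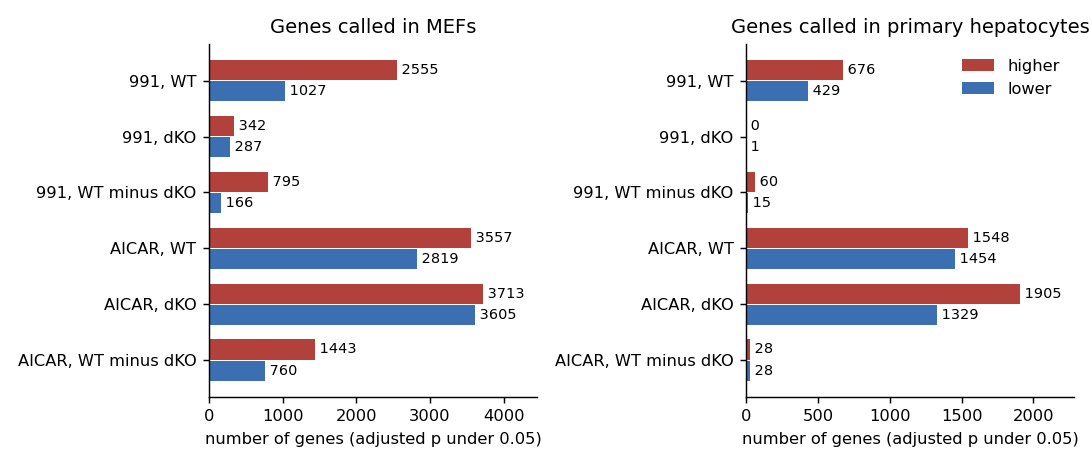
Number of genes called (horizontal axis, adjusted p under 0.05) higher or lower for each compound against vehicle in WT and dKO cells, and for the difference of the effects (WT minus dKO), in MEFs and primary hepatocytes. In dKO cells 991 left 342 higher and 287 lower in MEFs and 1 lower in hepatocytes. There AICAR left 3713 higher and 3605 lower in MEFs and 1905 higher and 1329 lower in hepatocytes.

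AICAR, which cells convert into an AMP analogue, changed far more genes in WT MEFs than 991 did at its dose. Flcn rose by 0.40 ± 0.07 (9.61 ± 0.04 against 9.21 ± 0.09, n = 4 each, adjusted p = 1.23e-05), with Fnip1 (1.01 ± 0.12) and Fnip2 (0.72 ± 0.06). Ccdc25 (1.93 ± 0.09), Txnip (1.86 ± 0.07), Klhl28 (1.57 ± 0.08), the transcription factor gene Klf11 (1.54 ± 0.09), Mss51 (1.53 ± 0.07), Zc3h12c (1.47 ± 0.09) and the RNA-binding gene Taf15 (1.28 ± 0.07) rose as well. Chac1, a glutathione-degrading enzyme induced by stress, fell by 2.56 ± 0.08 (adjusted p = 2.31e-21). Falls among genes above the median level were also those of Dido1 (-2 ± 0.06), Jrk (-1.92 ± 0.1), the inhibitor of transcription elongation Hexim1 (-1.66 ± 0.05), Jmjd4 (-1.65 ± 0.08), Tbcc (-1.62 ± 0.06), Nabp1 (-1.59 ± 0.06) and Ppp1r10 (-1.51 ± 0.09). In all, 6376 genes were called, 3557 higher and 2819 lower, with 219 and 344 changed by at least 1.5-fold, but after quantile normalization more were lower (3261) than higher (2983). Prkaa1, looked up after its values were seen, fell by 0.49 ± 0.1 (7.86 ± 0.14 against 8.35 ± 0.13, adjusted p = 0.000272).

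ATF4 targets fell in 14 of 24 and 1 rose with AICAR in WT MEFs (14 and 2 over the list alone), including Trib3 (-1.33 ± 0.09), the arginine transporter Slc7a1 (-1.10 ± 0.03) and Nupr1 (-0.83 ± 0.04). For the list, adjusted p was 7.29e-06, and 0.0311 with an estimated correlation. Inflammatory genes fell in 9 of 20 and rose in 3, the same over the list alone, including the chemokines Cxcl5 (-2.52 ± 0.13) and Ccl2 (-0.69 ± 0.04) and the prostaglandin synthase Ptgs2 (-0.95 ± 0.07). Camera gave adjusted p = 0.00445, and 0.0238 with an estimated correlation. Cholesterol genes rose in 14 of 20 and fell in 1 (15 and 1 over the list alone; Hsd17b7 1.10 ± 0.03, Fdft1 0.58 ± 0.03). They passed at adjusted p = 8.2e-11, and 0.0238 with an estimated correlation. 4 lists passed only with the preset correlation. TFEB and TFE3 targets rose in 20 of 38 and fell in 4 (20 and 5 over the list alone; Mitf -0.38 ± 0.09). Their adjusted p was 0.00479, and 0.385 with an estimated correlation. Immediate early genes fell in 11 of 20 and rose in 5, the same over the list alone (Dusp6 -1.11 ± 0.06, Klf6 0.75 ± 0.03). Their adjusted p was 0.00215, and 0.157 with an estimated correlation. Extracellular matrix genes fell in 8 of 17, the same over the list alone (Pdgfrb -1.12 ± 0.07, Col1a1 -0.29 ± 0.04). Their adjusted p was 0.00792, and 0.157 with an estimated correlation. YAP and SRF targets fell in 8 of 16 and rose in 1, the same over the list alone (Ccn2 -0.75 ± 0.04, Ankrd1 -0.71 ± 0.04). The list had adjusted p = 0.0131, and 0.385 with an estimated correlation.

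In dKO MEFs, AICAR left Prkaa1 (-0.17 ± 0.1, adjusted p = 0.201), Prkaa2 (0.10 ± 0.08, adjusted p = 0.363) and Flcn (0.07 ± 0.07, adjusted p = 0.421) uncalled, yet 7318 genes were called, 3713 higher and 3605 lower (3287 and 3960 after quantile normalization), with 303 and 697 changed by at least 1.5-fold. Taf15 (1.99 ± 0.07), Zc3h12c (1.67 ± 0.09), Klhl28 (1.63 ± 0.08) and Mss51 (1.57 ± 0.07) rose. Chac1 (-2.88 ± 0.08), the nuclear RNA Neat1 (-2.70 ± 0.05), the ERK phosphatase Dusp6 (-2.43 ± 0.06), Nrarp (-2.10 ± 0.1), Jrk (-2.09 ± 0.1) and Tbcc (-2.04 ± 0.06) fell. Calls shared with WT numbered 4588 in the same direction, against 1284.5 for independent calls, and 121 in opposite directions. Inflammatory genes fell in 10 of 20 and rose in 1 (11 and 1 over the list alone; Ptgs2 -1.18 ± 0.07, Csf1 -0.97 ± 0.04, but Il6 1.29 ± 0.1). As a list they passed at adjusted p = 0.00262, and 0.0294 with an estimated correlation. Immediate early genes fell in 12 of 20 and rose in 3, the same over the list alone (Egr2 -2.16 ± 0.09, Ier2 -1.17 ± 0.04). This gave adjusted p = 2.45e-05, and 0.0715 with an estimated correlation. ATF4 targets fell in 12 of 24 and rose in 2, the same over the list alone (Slc7a1 -1.32 ± 0.03, Ddit3 -1 ± 0.05). The list test gave adjusted p = 0.00262, and 0.241 with an estimated correlation. Cholesterol genes rose in 12 of 20 and fell in 4, the same over the list alone (Hsd17b7 0.75 ± 0.03, Insig1 -0.43 ± 0.06). Together they had adjusted p = 0.0019, and 0.241 with an estimated correlation. Genes of the unfolded protein response rose in 11 of 19 and fell in 2, the same over the list alone (Edem1 0.51 ± 0.05, Xbp1 -0.67 ± 0.04). Adjusted p was 0.0419, and 0.638 with an estimated correlation, and this list missed the threshold after quantile normalization (adjusted p = 0.29). YAP and SRF targets fell in 10 of 16 and rose in 5, the same over the list alone (Ccn2 -1.05 ± 0.04). For the list, adjusted p was 0.0419, and 0.638 with an estimated correlation.

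The AICAR interaction in MEFs called 2203 genes, 1443 higher and 760 lower for WT minus dKO, without Prkaa1 (-0.32 ± 0.15, adjusted p = 0.183) or Prkaa2 (-0.19 ± 0.12, adjusted p = 0.356). Flcn differed by 0.32 ± 0.09 (adjusted p = 0.0203), a call that was lost without a trend of the prior variance. Neat1 (1.66 ± 0.08), Txnip (1.37 ± 0.1), Dusp6 (1.32 ± 0.08), Phf20 (1.32 ± 0.05), the insulin receptor substrate Irs1 (1.28 ± 0.05), Sox4 (1.25 ± 0.05) and Bhlhe40 (1.18 ± 0.07) were higher for WT minus dKO. Trib3 (-1 ± 0.13), Esco1 (-0.87 ± 0.07), Galnt11 (-0.84 ± 0.09) and Sfrp2 (-0.77 ± 0.11) were lower. Immediate early genes were higher in 10 of 20, the same over the list alone (Egr2 1.58 ± 0.12, Myc 0.55 ± 0.05). Camera gave adjusted p = 3.46e-09, and 0.0166 with an estimated correlation. Cholesterol genes were higher in 9 of 20 (11 over the list alone; Mvd 0.52 ± 0.07, Insig1 0.52 ± 0.08). Adjusted p was 1.57e-06, and 0.102 with an estimated correlation. Matrix genes were lower in 4 of 17 (7 over the list alone; Col3a1 -0.56 ± 0.1), with adjusted p = 0.0294, and 0.259 with an estimated correlation (0.0602 after quantile normalization). Of the genes called with AICAR in WT MEFs, 666 (10.45%) were AMPK-dependent, 439 higher and 227 lower, and 77 of the 563 with a 1.5-fold change. Over those 563 genes the slope of the dKO change on the WT change was 1.053, and 144 genes were AMPK-dependent with both compounds.

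**Figure D3:**
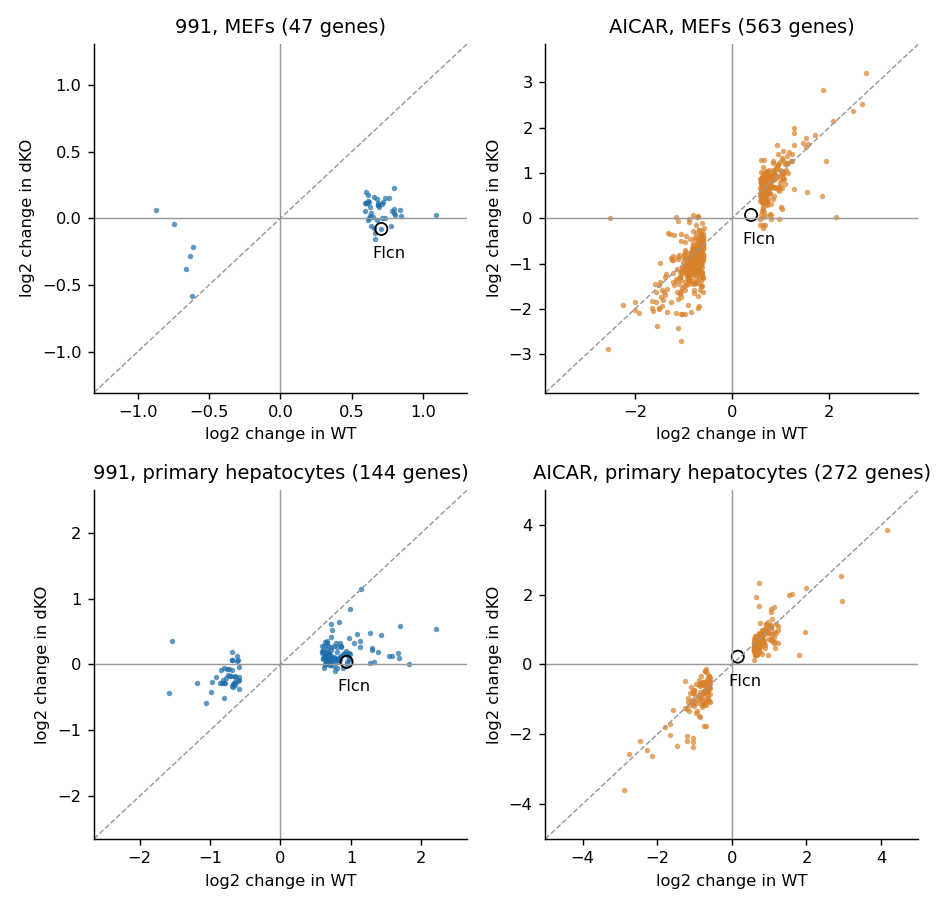
Log2 change against vehicle in dKO cells (vertical axis) and in WT cells (horizontal axis) for genes called in WT with at least a 1.5-fold change; each point is a gene, the dashed line marks equal effects and Flcn is circled whether called or not. The slope through 0 was 0.108 for 991 and 1.053 for AICAR in MEFs, and 0.212 and 0.975 in hepatocytes.

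In hepatocytes under vehicle, Prkaa1 stood at 4.52 ± 0.09 in dKO and 5.63 ± 0.13 in WT (n = 2 preparations each), a difference of -1.11 ± 0.09 that was not called (adjusted p = 0.194). It was called with every array as a sample (adjusted p = 4.44e-11), which takes technical replicates as samples. Without dKO preparation 1 or 2, where the spread comes from WT alone, the adjusted p was 0.0117 and 0.00682. Without WT preparation 1 or 2, where it comes from dKO alone, it was 0.0508 and 0.0808, and with a replicate block 0.245. Prkaa2 did not differ (9.60 ± 0.05 against 9.69 ± 0.03, adjusted p = 0.993), and again a probe set outside the deleted part checks nothing. With limma, 0 genes were called, and 846 had an unadjusted p under 0.05. Kupffer cell and macrophage markers, 15 genes, were lower in dKO with a median of -0.41 (6 lower over the list alone, adjusted p = 1.06e-11, and 0.657 with an estimated correlation). Beside this shift in markers of another cell type, TFEB and TFE3 targets were lower (median -0.15, 3 lower over the list alone, adjusted p = 3.77e-13, and 0.586 with an estimated correlation) and genes of fatty acid oxidation higher (median 0.12, 2 higher over the list alone, adjusted p = 2.24e-05, and 0.586 with an estimated correlation). Unfolded protein response genes (median -0.34, adjusted p = 1.69e-05), hypoxia genes (-0.13, 0.0122) and glycolysis genes (-0.08, 0.0353) passed as lower, and p53 targets (0.06, 0.0124) and YAP and SRF targets (0.07, 0.0211) as higher. None of these 5 lists had a called member, and each had adjusted p = 0.657 with an estimated correlation.

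With 991, WT hepatocytes raised Flcn by 0.94 ± 0.09 (10.09 ± 0.04 against 9.15 ± 0.06, n = 2 each, adjusted p = 0.000223). The kinase gene Pdk4, a brake on glucose oxidation, rose by 2.21 ± 0.24 and the lipid droplet gene Hilpda by 1.69 ± 0.12. Other large rises were those of Rab30 (1.59 ± 0.16), the immediate early gene Egr1 (1.53 ± 0.21), Snai2 (1.39 ± 0.12), Zfp385b (1.33 ± 0.08) and Grpel2 (1.30 ± 0.1). G6pc, which encodes the catalytic subunit of glucose-6-phosphatase in glucose output, fell by 1.54 ± 0.24 (adjusted p = 0.00342). Falls were also called for the heat shock gene Hspa1b (-1.59 ± 0.25), Proser2 (-1.19 ± 0.17), Cited2 (-1.06 ± 0.06), Sox4 (-0.99 ± 0.07), the aryl hydrocarbon receptor Ahr (-0.97 ± 0.08), Enc1 (-0.91 ± 0.11) and the YAP regulator Amotl2 (-0.85 ± 0.05). There were 1105 calls, 676 higher and 429 lower, with 103 and 41 changed by at least 1.5-fold. Without the preparation as a block 166 were called, without Atf3, Hspa1b, G6pc, Proser2 and Enc1 among others, and without WT preparation 2 the count was 117 (537 without preparation 1).

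TFEB and TFE3 targets rose in 17 of 38 and none fell with 991 in WT hepatocytes (27 rose over the list alone), with a median of 0.20: beside Flcn these were Fnip2 (0.78 ± 0.07), the proton pump subunit Atp6v1b2 (0.73 ± 0.07) and Neu1 (0.67 ± 0.06). The list passed at adjusted p = 3.36e-13, and had 0.341 with an estimated correlation. ATF4 targets rose in 7 of 24 (8 over the list alone), including Atf3 (1.43 ± 0.26), Nupr1 (1.29 ± 0.08), Ddit3 (1.28 ± 0.29) and Ppp1r15a (1.13 ± 0.15). They passed at adjusted p = 0.000191, and 0.402 with an estimated correlation. Immediate early genes rose in 6 of 20 (8 over the list alone; Ier3 0.48 ± 0.09, Myc 0.44 ± 0.05). The list had adjusted p = 3.9e-05, and 0.364 with an estimated correlation. Genes of fatty acid oxidation rose in 6 of 18 and fell in 1 (8 and 2 over the list alone), with Pdk4, the fasting hormone Fgf21 (0.98 ± 0.19) and Creb3l3 (0.54 ± 0.05), and adjusted p = 0.00566, and 0.404 with an estimated correlation. Cholesterol genes rose in 5 of 20 (7 over the list alone), led by Insig1 (0.77 ± 0.06). As a list they passed at adjusted p = 0.00215, and 0.464 with an estimated correlation. YAP and SRF targets fell in 5 of 16 (7 over the list alone; Ajuba -0.74 ± 0.04, Nuak2 -0.46 ± 0.06). This gave adjusted p = 5.82e-06, and 0.149 with an estimated correlation. Inflammatory genes fell in 8 of 20 and rose in 2, the same over the list alone (Tnfaip3 -0.71 ± 0.07, Ccl20 -0.70 ± 0.1, Ccl7 0.72 ± 0.07). The list test gave adjusted p = 0.00149, and 0.364 with an estimated correlation. NRF2 genes fell in 4 of 17 and rose in 2 (6 and 2 over the list alone; Gclc -0.31 ± 0.03, Hmox1 0.44 ± 0.11). Together they had adjusted p = 0.000173, and 0.149 with an estimated correlation. AMPK subunits and upstream kinases were lower with 1 of 9 called (2 lower over the list alone; Prkag3 -0.58 ± 0.08). For the list, adjusted p was 0.000346, and 0.149 with an estimated correlation. Also lower were p53 targets (4 down and 2 up of 17, 8 and 4 over the list alone; Phlda3 -0.57 ± 0.07; adjusted p = 0.0382, and 0.464 with an estimated correlation), purine synthesis genes (Nt5e -0.42 ± 0.06; adjusted p = 0.00566, and 0.402 with an estimated correlation) and ribosome biogenesis genes (Nop56 -0.19 ± 0.04; adjusted p = 0.000708, and 0.402 with an estimated correlation). These last 3 lists missed the threshold after quantile normalization.

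In dKO hepatocytes 991 left Prkaa1 (0 ± 0.1, adjusted p = 0.998), Prkaa2 (0 ± 0.06, adjusted p = 0.998) and Flcn (0.04 ± 0.09, adjusted p = 0.998) uncalled. Cited2, a transcriptional coregulator, was the only gene called, and it fell by 0.58 ± 0.06 (adjusted p = 0.0145), a call that was lost without a trend of the prior variance, with only genes at or above the median level, or without the preparation as a block. The unadjusted p was under 0.05 for 819 genes, and across all genes the changes with 991 in WT and dKO had r = 0.458. Genes of fatty acid oxidation were higher by a median of 0.12 (6 over the list alone, adjusted p = 5.5e-08, and 0.328 with an estimated correlation) and ATF4 targets by 0.14 (1 over the list alone, adjusted p = 2.67e-06, and 0.628 with an estimated correlation). YAP and SRF targets were lower, with a median of -0.11 (4 over the list alone, adjusted p = 4.75e-07, and 0.118 with an estimated correlation). Cholesterol genes were lower, with a median of -0.04 (adjusted p = 0.0285, and 0.875 with an estimated correlation), but not within preparation 1, where the median was 0.01, or after quantile normalization (adjusted p = 0.163).

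The 991 interaction in hepatocytes called 75 genes, 60 higher and 15 lower for WT minus dKO, and 1416 had an unadjusted p under 0.05. Prkaa1 (-0.35 ± 0.14, adjusted p = 0.574) and Prkaa2 (-0.02 ± 0.08, adjusted p = 0.968) were not among them. Flcn differed by 0.90 ± 0.13 (adjusted p = 0.0126), Rab30 by 1.46 ± 0.23, Zfp385b by 1.30 ± 0.11, Snai2 by 1.19 ± 0.17, Hilpda by 1.11 ± 0.16, Nupr1 by 1.08 ± 0.12, Grpel2 by 1.05 ± 0.14 and the membrane fusion gene Stx3 by 0.93 ± 0.16. G6pc (-1.90 ± 0.34), Tsc22d1 (-0.77 ± 0.11), Egln3 (-0.76 ± 0.13), Irs1 (-0.75 ± 0.13) and Ajuba (-0.58 ± 0.06) were lower. All 75 were AMPK-dependent, 6.79% of the 1105 WT calls (the rest undecided) and 56 of the 144 with a 1.5-fold change. The slope over those 144 was 0.212. Only 3 genes were called without the preparation as a block, a setting that lost Flcn, and 31 without a trend of the prior variance.

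TFEB and TFE3 targets had a larger 991 effect in WT hepatocytes in 5 of 38 (14 over the list alone; Fnip2 0.68 ± 0.09, Rragd 0.67 ± 0.12, Neu1 0.65 ± 0.09). Camera gave adjusted p = 3.22e-16, and 0.251 with an estimated correlation. Cholesterol genes did so in 1 of 20 (6 over the list alone; Insig1 0.87 ± 0.08). Adjusted p was 2.11e-06, and 0.378 with an estimated correlation. Immediate early genes did so in 1 of 20 (4 over the list alone; Dusp1 0.37 ± 0.06). They passed at adjusted p = 0.00013, and 0.378 with an estimated correlation. Interferon genes were higher in 1 of 17 (3 over the list alone; Rsad2 0.74 ± 0.12; adjusted p = 0.0327, and 0.723 with an estimated correlation), but the list's median was -0.13 within preparation 2. Lower lists were NRF2 genes (3 over the list alone; adjusted p = 1.53e-05), AMPK subunits (1 over the list alone; 0.00013) and YAP and SRF targets (2 of 16 called, Amotl2 -0.57 ± 0.08; 0.00239), with adjusted p = 0.179, 0.179 and 0.21 with an estimated correlation. Inflammatory genes were lower in 1 of 20 (7 lower and 1 higher over the list alone; Tnfaip3 -0.54 ± 0.1). The list had adjusted p = 0.00072, and 0.349 with an estimated correlation. Ribosome biogenesis, purine and bile acid genes were also lower as lists (adjusted p = 0.000798, 0.0327 and 0.0327, and 0.409, 0.536 and 0.685 with an estimated correlation), with Baat (-0.38 ± 0.07) as their only called member, and these 3 missed the threshold after quantile normalization.

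AICAR in WT hepatocytes did not change Flcn (0.16 ± 0.09, adjusted p = 0.264), and the change was 0.37 in preparation 1 and -0.06 in preparation 2. H3f3b rose by 4.17 ± 0.2 (adjusted p = 4.65e-07), Fos by 2.96 ± 0.54, Egr1 by 2.91 ± 0.21, Gadd45g by 1.99 ± 0.25, the gluconeogenic gene Pck1 by 1.23 ± 0.26, Cyp26a1 by 1.22 ± 0.17 and the phosphatidate phosphatase gene Lpin1 by 1.19 ± 0.18. Neat1 fell by 2.90 ± 0.19, the noncoding RNA Dancr by 2.76 ± 0.12, Cxcl1 by 2.15 ± 0.12, Tmem186 by 1.80 ± 0.15, Ccnyl1 by 1.57 ± 0.06 and Ddit3 by 1.46 ± 0.29. Prkaa1 fell by 0.33 ± 0.1 (adjusted p = 0.0474), and by 0.35 ± 0.1 with 991 (adjusted p = 0.0714), also looked up later. Of 3002 calls, 1548 were higher and 1454 lower, 155 and 117 by at least 1.5-fold. In dKO hepatocytes AICAR called 3234, 1905 higher and 1329 lower, with 200 and 172 of at least 1.5-fold. There too Prkaa1 (0.12 ± 0.1), Prkaa2 (-0.04 ± 0.06) and Flcn (0.22 ± 0.09) were not called (adjusted p = 0.489, 0.688 and 0.114). H3f3b (3.87 ± 0.2), Egr1 (2.55 ± 0.21), Gadd45g (2.20 ± 0.25), Fos (1.81 ± 0.54), the growth factor gene Hbegf (1.64 ± 0.13) and Pdk4 (1.58 ± 0.24) rose. Neat1 (-3.60 ± 0.19), Cxcl1 (-2.62 ± 0.12), Dancr (-2.58 ± 0.12), Rpl12 (-2.37 ± 0.09), Ddit3 (-2.33 ± 0.29) and Dusp1 (-2.09 ± 0.04) fell. The genotypes shared 1820 calls in the same direction, against 268.3 for independent calls, and 7 in opposite directions. Without the preparation as a block the counts were 724 in WT and 1093 in dKO. Whether the probe sets of H3f3b (6.51 with dKO vehicle, median gene 6.87) and Rpl12 read mature mRNA was not tested.

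Bile acid synthesis and transport genes rose in 11 of 13 with AICAR in both genotypes (12 in WT, and 11 with 1 lower in dKO, over the list alone). Among them were Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.13 ± 0.31 in WT), and Cyp8b1 (0.82 ± 0.12 in WT, 0.94 ± 0.12 in dKO). As a list they passed at adjusted p = 5.24e-07 and 8.52e-06 in WT and dKO, and 0.348 and 0.365 with an estimated correlation. Gluconeogenesis genes rose in 8 of 13 in WT and 9 in dKO (11, and 10 with 1 lower, over the list alone; Pck1 0.99 ± 0.26 and the glucose-6-phosphate transporter Slc37a4 0.56 ± 0.06 in dKO). This gave adjusted p = 1.48e-05 and 0.00115 in WT and dKO, and 0.348 and 0.413 with an estimated correlation. NRF2 genes fell in 11 of 17 in WT (12 over the list alone; the cystine transporter Slc7a11 -1.03 ± 0.07, Abcc4 -0.90 ± 0.12, Nqo1 -0.58 ± 0.09). The list test gave adjusted p = 1.45e-11, and 0.0425 with an estimated correlation. In dKO 7 fell and 1 rose (8 and 1 over the list alone). Together they had adjusted p = 0.000217, and 0.265 with an estimated correlation. Inflammatory genes fell in 5 and rose in 2 of 20 in WT, and 8 fell and 3 rose in dKO (6 and 2, and 8 and 4, over the list alone; Ccl20 -0.76 ± 0.1 and -0.82 ± 0.1). For the list, adjusted p was 0.00262 and 0.0013 in WT and dKO, and 0.348 and 0.365 with an estimated correlation. Interferon genes rose in 5 of 17 in WT and 4 in dKO (7 and 6 over the list alone; Usp18 0.72 ± 0.08 and 0.85 ± 0.08). Camera gave adjusted p = 0.00714 and 0.0311 in WT and dKO, and 0.52 and 0.704 with an estimated correlation. Glycolysis genes rose in 7 of 20 in WT, and 6 rose and 1 fell in dKO (7, and 8 with 1 lower, over the list alone; Pfkp 0.71 ± 0.06 and 0.67 ± 0.06). They passed at adjusted p = 0.0329 and 0.00866 in WT and dKO, and 0.348 and 0.365 with an estimated correlation. Fatty acid oxidation genes rose in 7 and fell in 1 of 18 in WT, and 8 rose and 2 fell in dKO (9 and 3, and 11 and 2, over the list alone; Ppara 0.71 ± 0.1 and 0.63 ± 0.1). Their adjusted p was 0.049 and 0.0192 in WT and dKO, and 0.404 and 0.413 with an estimated correlation, and the list missed the threshold in dKO after quantile normalization (adjusted p = 0.0704). Cell cycle genes were lower as a list in both genotypes (2 up and 6 down of 25 in WT, 3 up and 7 down in dKO; 3 and 7, and 3 and 8, over the list alone), although Rrm2 (1.06 ± 0.23 in both) and Ccnb2 (0.73 ± 0.06 and 1.67 ± 0.06) rose. The list had adjusted p = 0.0384 and 0.0192 in WT and dKO, and 0.348 and 0.365 with an estimated correlation.

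Other lists passed for AICAR in a single hepatocyte genotype, which does not show that the genotypes differ. In WT, unfolded protein response genes fell in 9 of 19 (13 over the list alone; Creld2 -0.82 ± 0.22, Pdia4 -0.69 ± 0.18; adjusted p = 7.63e-08, and 0.348 with an estimated correlation), and ribosome biogenesis genes in 7 of 20 (8 over the list alone; Nop56 -0.49 ± 0.04; adjusted p = 9.1e-07, and 0.348 with an estimated correlation). ATF4 targets fell in 10 of 24 and rose in 4 (13 and 7 over the list alone; adjusted p = 0.00714, and 0.394 with an estimated correlation). Purine genes fell in 3 of 22 and rose in 2 (4 and 2 over the list alone; Pfas -0.51 ± 0.07, Slc29a1 0.48 ± 0.1; adjusted p = 0.0145, and 0.363 with an estimated correlation). Cholesterol genes fell in 4 of 20 (6 lower and 1 higher over the list alone; Msmo1 -0.46 ± 0.05; adjusted p = 0.0369, and 0.495 with an estimated correlation). The purine and cholesterol lists missed the threshold after quantile normalization, where the cholesterol median turned from -0.02 to 0.001. In dKO, hypoxia genes rose in 9 of 15 and fell in 1 (12 and 1 over the list alone; Egln3 0.81 ± 0.09; adjusted p = 0.000876, and 0.365 with an estimated correlation), and clock genes rose in 6 of 16 and fell in 1 (9 and 2 over the list alone; Dbp 0.47 ± 0.09; adjusted p = 0.0192, and 0.365 with an estimated correlation). Markers of several liver cell types rose in the same samples. Hepatocyte secreted protein genes rose in 5 of 14 in WT and 6 in dKO (7 with 1 lower in each over the list alone; Fga 0.41 ± 0.07 and 0.53 ± 0.07). As a list they passed at adjusted p = 0.00631 and 0.00543 in WT and dKO, and 0.394 and 0.467 with an estimated correlation. Endothelial markers rose in 5 of 14 in WT and 7 in dKO (Stab2 0.69 ± 0.07 and 0.49 ± 0.07). This gave adjusted p = 0.00479 and 0.0013 in WT and dKO, and 0.348 and 0.265 with an estimated correlation. Kupffer cell markers rose in 10 of 15 in dKO (11 over the list alone; Cd68 0.45 ± 0.08, Vsig4 0.43 ± 0.09; adjusted p = 0.000689, and 0.413 with an estimated correlation).

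**Figure D4:**
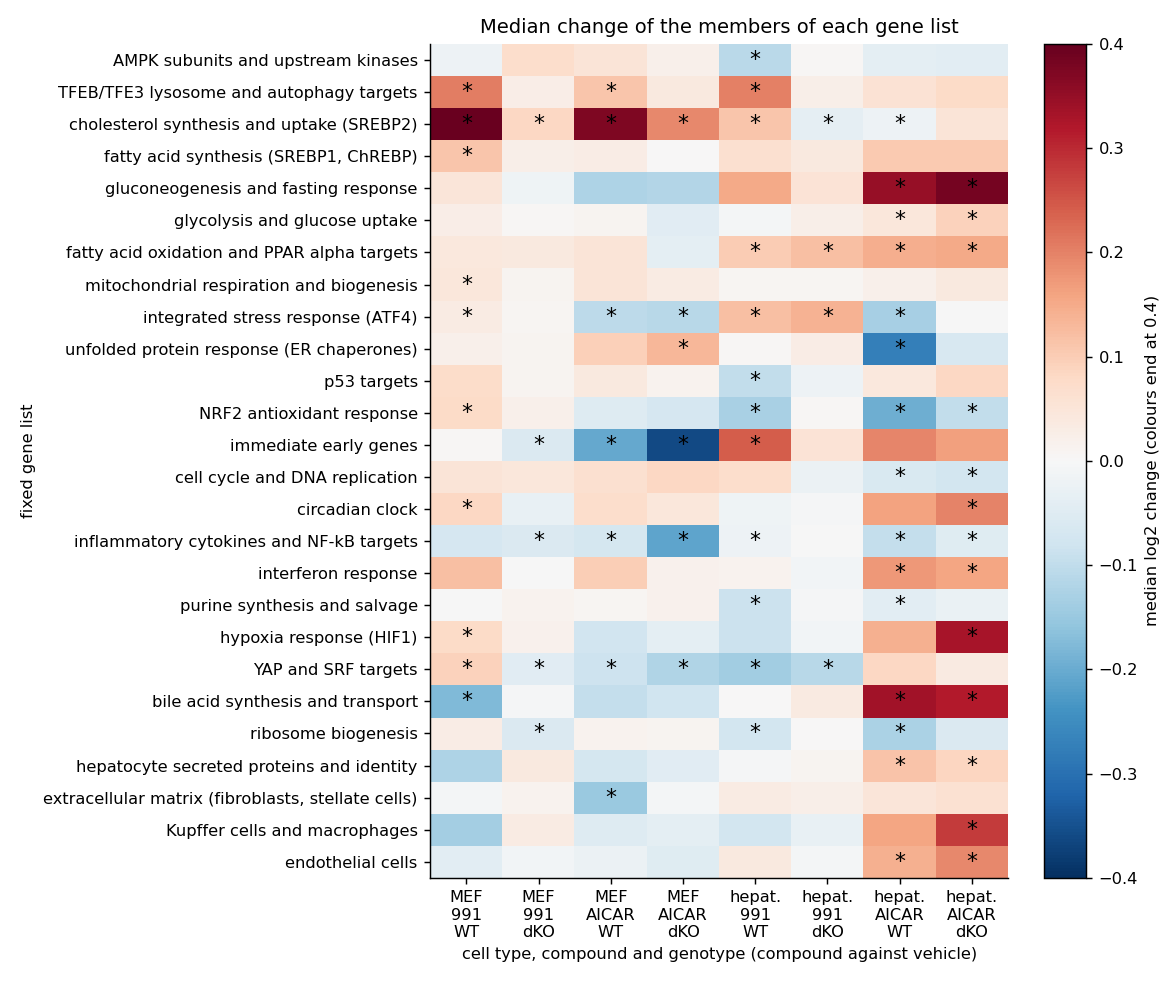
Median log2 change against vehicle (colour) of the measured members of each fixed gene list (vertical axis) in each cell type, compound and genotype (horizontal axis); a star marks a list that passed at an adjusted p under 0.05 with the preset correlation, and lists that passed in none of these 8 comparisons are left out. The TFEB and TFE3 list was at 0.20 with 991 in WT cells of both types, and the bile acid list at 0.34 in WT and 0.32 in dKO hepatocytes with AICAR.

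The AICAR interaction in hepatocytes called 56 genes, 28 higher and 28 lower for WT minus dKO, and 1592 had an unadjusted p under 0.05. Prkaa1 (-0.44 ± 0.14, adjusted p = 0.378), Prkaa2 (0 ± 0.08, adjusted p = 0.997) and Flcn (-0.07 ± 0.13, adjusted p = 0.923) were not called. Dusp1, a phosphatase of MAP kinases, differed by 1.76 ± 0.06 (adjusted p = 7.86e-08), Rpl12 by 1.33 ± 0.12, Trib1 by 1.09 ± 0.15, Ier3 by 1.06 ± 0.13 and Ccnt2 by 1.06 ± 0.16. Rnf225 (-1.28 ± 0.22), Cdk12 (-0.92 ± 0.11) and Sertad1 (-0.88 ± 0.08) were lower. Immediate early genes were higher in 3 of 20 (4 higher and 1 lower over the list alone; Myc 0.54 ± 0.06). The list test gave adjusted p = 0.00105, and 0.622 with an estimated correlation. As lists, unfolded protein response (adjusted p = 1.09e-06, 1 lower over the list alone), NRF2 (7.68e-06, 4 lower), ribosome biogenesis (0.000227, 1 called, Nop58 -0.40 ± 0.07), cholesterol (0.00105, 4 lower), ATF4 (0.00344), Kupffer cell (0.00532) and hypoxia genes (0.0379, 3 lower) were lower. With an estimated correlation NRF2 had adjusted p = 0.165, Kupffer cells 0.762 and the other 5 adjusted p = 0.622, and cholesterol, ATF4, hypoxia and ribosome genes missed the threshold after quantile normalization. Without WT preparation 2 the Kupffer median turned to 0.02. Only 10 AICAR calls in WT hepatocytes (0.33%; 8 higher, 2 lower) were AMPK-dependent, 2 of them among the 272 with a 1.5-fold change, and the slope over those 272 was 0.975. With the median filter 19 genes were called, and without the block 16. Probe sets outside the gene table differed more often: 535 of 10092 without a single gene name were called (363 higher and 37 lower by 1.5-fold), and 497 of 16752 other probe sets of named genes (282 and 55).

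Both compounds were compared directly in WT cells at doses that differ. In MEFs Flcn was higher with 991 than with AICAR by 0.31 ± 0.07 (adjusted p = 0.000876), and 5086 genes differed, 3029 higher and 2057 lower with 991. Chac1 (2.93 ± 0.08), Jrk (1.85 ± 0.11), Trib3 (1.64 ± 0.1) and Nabp1 (1.64 ± 0.07) were higher with 991. Mss51 (-1.50 ± 0.07), Ccdc25 (-1.28 ± 0.1), Rbm15 (-1.24 ± 0.05) and Txnip (-1.13 ± 0.08) were lower. ATF4 targets were higher in 13 of 24 (14 over the list alone; Ddit3 1.29 ± 0.06) and inflammatory genes higher in 8 and lower in 1 of 20 (10 and 2 over the list alone; Ptgs2 1.19 ± 0.08, Cxcl5 1.64 ± 0.14, Il6 -0.70 ± 0.11). The 2 lists had adjusted p = 2.58e-09 and 0.00244, and 0.0108 and 0.0206 with an estimated correlation. Higher only with the preset correlation were YAP and SRF targets (10 up, 2 down; adjusted p = 0.000195, and 0.171 with an estimated correlation), TFEB and TFE3 targets (16 up; 0.00106, and 0.272), hypoxia genes (7 up, Adm 0.79 ± 0.09; 0.00219, and 0.171), NRF2 genes (10 up, Gclc 0.44 ± 0.04; 0.00244, and 0.171) and immediate early genes (11 up, 5 down; 0.00244, and 0.174). In hepatocytes Flcn was higher with 991 by 0.78 ± 0.09 (adjusted p = 0.000142), and 3415 genes differed, 1646 higher and 1769 lower. Neat1 (3.30 ± 0.19), Dancr (2.74 ± 0.12), Ddit3 (2.74 ± 0.29) and Nupr1 (1.91 ± 0.08) were higher with 991. H3f3b (-4.24 ± 0.2), G6pc (-2.27 ± 0.24), Fos (-1.89 ± 0.54) and Gadd45g (-1.78 ± 0.25) were lower.

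Of 16 lists that differed between the compounds in WT hepatocytes, none passed with an estimated correlation. Bile acid genes were lower with 991 in 12 of 13 (Cyp7a1 -1.64 ± 0.31; adjusted p = 1.94e-08, and 0.296 with an estimated correlation), hepatocyte secreted protein genes in 7 of 14 (3.02e-05, and 0.304), and YAP and SRF targets in 7 with 1 higher of 16 (Amotl2 -1.37 ± 0.05; 1.58e-05, and 0.212). Lower too were p53 targets (8 of 17, 1 higher, Sesn1 -1.14 ± 0.17; 0.00407, and 0.304), glycolysis genes (7 of 20, 3 higher, Pkm -0.93 ± 0.06; 0.0127, and 0.296), hypoxia genes (5 of 15, 2 higher, Egln3 -1.18 ± 0.09; 0.0127, and 0.304), endothelial markers (6 of 14, Stab2 -0.78 ± 0.07; 0.00323, and 0.241) and Kupffer cell markers (6 of 15, 2 higher; 0.00394, and 0.428). Higher with 991 were ATF4 targets (13 of 24, 1 lower; 1.64e-07, and 0.296), unfolded protein response genes (10 of 19, Pdia4 0.77 ± 0.18; 5.84e-06, and 0.304), TFEB and TFE3 targets (14 of 38; 1.35e-05, and 0.341), cholesterol genes (9 of 20, Insig1 0.94 ± 0.06; 0.000489, and 0.341) and NRF2 genes (7 of 17, 2 lower, Slc7a11 0.93 ± 0.07; 0.00057, and 0.221). Ribosome biogenesis genes (5 of 20; 0.0234, and 0.428), markers of cholangiocytes and epithelium (3 of 10, Cldn4 1.15 ± 0.16; 0.0234, and 0.296) and cell cycle genes (6 of 25, 2 lower, Rrm2 -1.06 ± 0.23; 0.0497, and 0.304) completed the higher lists. Targets of the aryl hydrocarbon and xenobiotic receptors, 14 measured genes, passed in no comparison of either cell type, with adjusted p = 0.0721 at the least, in dKO against WT hepatocytes.

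Calls shared between the compounds in WT cells use the same vehicle arrays, which alone makes changes correlate across genes. In MEFs 1768 genes were called in the same direction with both (1355 higher, 413 lower) and 353 in opposite directions, against 658.7 and 596.7 for independent calls. With vehicle arrays split between the compounds 863.5 were shared. The covariance was 0.0128, against 0.00277 in simulations without an effect and 0.0106 split, but r was 0.34 and did not exceed the simulated 0.463 (0.265 split). Among the shared genes were Hsd17b7 (0.69 ± 0.03 with 991, 1.10 ± 0.03 with AICAR), Acss2 (0.76 ± 0.09, 0.98 ± 0.08), Fnip1 and Fnip2 given above, Ifit1 (0.84 ± 0.09, 0.81 ± 0.09) and Cxcl5 (-0.88 ± 0.14, -2.52 ± 0.13). In hepatocytes 259 were shared (129 higher, 130 lower) and 135 opposite, against 91.8 and 90.5 for independent calls. With split vehicle arrays 242 were shared. The covariance was 0.00613 against 0.0025 simulated and 0.00495 split, and r was 0.208 against 0.5 and 0.162. Egr1, Pdk4, Fgf21 and the interferon gene Rsad2 (0.86 ± 0.09 with 991, 0.77 ± 0.09 with AICAR) rose with both, and Sox4 fell with both (-0.99 ± 0.07 and -1 ± 0.07).

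Across the cell types, 991 in WT shared 315 calls in the same direction (274 higher, 41 lower) and 71 in opposite directions, against 119.2 and 98.4 for independent calls. Flcn, Fnip2, Neu1, Ddit3, Stx3 (0.68 ± 0.05 in MEFs, 0.94 ± 0.12 in hepatocytes), the cystine transporter of lysosomes Ctns (0.61 ± 0.1, 0.80 ± 0.07) and Gadd45a (0.63 ± 0.09, 0.55 ± 0.11) rose in both. AICAR shared 704 in the same direction, against 528 for independent calls, and 733 in opposite directions, against 524.1, with Neat1, Tmem186 (-0.96 ± 0.1, -1.80 ± 0.15), Hypk (-1.34 ± 0.13, -1.65 ± 0.09) and Lpin1 (0.86 ± 0.07, 1.19 ± 0.18) among the former. With 991, 24 genes were AMPK-dependent in both cell types, against 2.8 for independent interaction calls. These were Aacs, Ankrd12, Atp6v1b2, Ctns, Flcn, Fnip2, Gas2l3 (up 0.28 ± 0.05 in dKO MEFs too), Gnpda1, Grpel2, Hps4, Insig1, Mfsd11, Neu1, Ostm1, Pim1, Rhobtb1, Rhoq, Slc20a1, Slf2, Snx30, St3gal4, Stx3, Tifa and Uap1l1. Most depend on the hepatocyte model: in hepatocytes 13 stayed AMPK-dependent without a trend of the prior variance, 1 without the preparation as a block, and 1 to 7 when a preparation was left out. Of the 24, Flcn, Fnip2, Mfsd11, Pim1 and Stx3 were also AMPK-dependent with AICAR in MEFs, and 0 genes were so with both compounds in hepatocytes.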

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

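The tests of array width, of chromosomes X and Y and of Xist were chosen only after the result was seen. The others were fixed before, except the regrouping after quantile normalization.

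AICAR changed as many genes in dKO as in WT cells, which remaining AMPK activity or normalization drift with intensity could give. Of called 1.5-fold changes, 91.7% in MEFs (917 of 1000) and 95.2% in hepatocytes (354 of 372) stayed that large without the intensity trend. That excludes the drift for these, but smaller calls were not tested. If AMPK activity remained, 991 in WT should move the same genes, but the slope of the 991 change in WT on the AICAR change in dKO was 0.005 in MEFs and 0.05 in hepatocytes. Both were under the 0.3 fixed beforehand, which argues against an AMPK that 991 also activates as the main cause of these changes as a set. It does not exclude a part for single genes. At its dose 991 changed only 47 genes by 1.5-fold in WT MEFs and 144 in WT hepatocytes, which by itself makes a high slope unlikely. Other targets of AICAR may account for these changes, which these data cannot separate; without the preparation block 1093 genes were called in dKO hepatocytes, 1070 of them also with it.

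Small 991 calls in WT MEFs may come from arrays whose values spread more widely. Of 3535 calls under 1.5-fold, 22.9% (810) stayed called in the same direction with array width as a covariate and 50.6% (1789) after quantile normalization. All 47 calls of at least 1.5-fold stayed with both (100%), which excludes width as the whole cause of these calls, but only 35 of them (74.5%) stayed at 1.5-fold after the trend of change on intensity was removed. WT vehicle replicate 2 had an interquartile range of 3.74, against 3.58 to 3.64 in the other WT vehicle arrays and 3.73 to 3.89 with 991. In WT, width also moves with the treatment, so the covariate may remove real effects and the small calls stay open.

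The difference between dKO and WT MEFs with vehicle could come from AMPK loss, embryo sex or the origin of each line. Xist differed by -6.39 ± 0.12, which AMPK loss does not give, so AMPK loss cannot be the whole cause. Of 2159 genes with a 1.5-fold difference 67 lie on X and 0 on Y (3.1%, against 3.44% of all genes). Xist goes with different sexes, the 0 on Y does not, and sex effects on other genes were not tested. With only technical replicates, these arrays may not tell the causes apart: all 4 per genotype gave the same direction for Xist.

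Regrouping the same arrays at random asks how many groupings call as many genes as the real one. For 991 in WT MEFs it was 2 of 35, with 3582 real calls and 3901 in the highest other split, in which WT vehicle replicate 2 joined the 991 arrays. After quantile normalization the real count was 2322 and the highest other 1751, so 1 of 35. The remaining comparisons with 35 splits each gave 1: AICAR in WT (6376 real, highest other 1761), 991 in dKO (629, 1), AICAR in dKO (7318, 0), 991 against AICAR (5086, 3259) and dKO against WT (8597, 0). With 100 splits the 991 interaction gave 2 (961, 1363, with the same WT array moved) and the AICAR interaction 1 (2203, 1384). The hepatocytes, with 2 preparations per genotype, allow no such test.

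The effects differed between the genotypes for 961 genes with 991 and 2203 with AICAR in MEFs, and for 75 and 56 in hepatocytes. In hepatocytes with AICAR, 560 probe sets without a single gene name were lower by at least 1.5-fold in WT and 948 in dKO. Among 85 groups checked for a far value 7 had one, where chance alone gives about 1 in 20. MEF dKO vehicle replicate 4 had a correlation with its group of 0.9989, against 0.9992 for the others. Hepatocyte WT 991 preparation 1, technical replicate 3, had Flcn at 9.82 (others 10.07 to 10.17) and Prkaa1 at 4.93 (5.30 to 5.43). Hepatocyte dKO AICAR preparation 2, technical replicate 1, had Prkaa1 at 4.21 (4.61 to 4.77) and an interquartile range of 3.40 (3.49 to 3.51). Prkaa2 was 9.85 in WT vehicle preparation 1, technical replicate 1 (9.67 to 9.70), and 9.75 in dKO vehicle preparation 2, technical replicate 5 (9.57 to 9.62).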

How the results depend on the processing

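Array width as a covariate and the crossed block were chosen only after the result was seen; all other settings were fixed before. The MEF counts for 991 against vehicle rest on few arrays and on a width that moves with 991 in WT, and the hepatocyte counts rest on the preparation block: without it most fall, and with technical replicates as samples they rise, since those do not measure the spread between preparations. Named genes stayed as they were, called or not, in 654 of 671 cases after quantile normalization and in 148 of 335 without the preparation block, and lists still passed in 115 of 143 and 47 of 79.

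In MEFs 991 called 2322 genes in WT after quantile normalization and 1101 with width as a covariate (857 of them called before), against 3582. In dKO MEFs 991 called 344 without a trend of the prior variance and 1210 with width, against 629. The 991 interaction called 382 with width, against 961. Calls shared by the compounds in MEFs were 1172 after quantile normalization and 663 with width, against 1768. A block by technical replicate number moved no count by more than 1.5 times.

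In hepatocytes without the preparation block the counts were 166 for 991 in WT (1105 with it), 724 for AICAR in WT (3002), 0 for 991 in dKO (1), 1093 for AICAR in dKO (3234), 3 for the 991 interaction (75), 16 for the AICAR interaction (56), 1303 for 991 against AICAR (3415) and 23 shared by the compounds (259). Calls shared with MEFs were then 69 for 991 and 210 for AICAR. With every array as a sample the counts were 5765, 7686, 783, 7131, 2111, 2317, 6976 and 2450 in the same order, 860 and 1600 shared with MEFs, and 2414 for dKO against WT. Within preparation 1 they were 3198, 6036, 554, 6814, 1103, 2593, 6550 and 1295, and within preparation 2 5385, 7039, 546, 5446, 2233, 3354, 5470 and 2577. For dKO against WT a block by preparation number called 0 and the crossed block 1462, but that pairing was picked because its deviations correlate, which shrinks the residual, so it supports no call. The 991 interaction called 31 genes without a trend and 39 with the mean of all probe sets, the AICAR interaction called 19 with only genes at or above the median, and 991 in dKO called 0 without a trend or with only those genes.

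Leaving out 1 array or preparation gave these lowest and highest counts. In MEFs they were 1889 and 4802 for 991 in WT, 5627 and 6660 for AICAR in WT, 302 and 539 for 991 in dKO, 6711 and 7434 for AICAR in dKO, 501 and 1712 for the 991 interaction, 1667 and 2261 for the AICAR interaction, 4280 and 4997 for 991 against AICAR, 8191 and 8557 for dKO against WT, and 1037 and 2482 shared. In hepatocytes they were 117 and 537, 943 and 1603, 0 and 1, 1035 and 1689, 11 and 25, 25 and 81, 1296 and 2010, 0 and 21, and 34 and 116 in the same order.

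With the mean of all probe sets the direction turned for Tomm20 with 991 in WT MEFs (0.011), Col5a1 in the MEF AICAR interaction (0.012), and Angptl4 (0.003) and Per2 (-0.22, adjusted p = 0.053) with AICAR in dKO hepatocytes. The cholesterol list for 991 in dKO hepatocytes turned to 0.008 within preparation 1 and without dKO preparation 2, against -0.085 without dKO preparation 1. The interferon list in the hepatocyte 991 interaction turned to -0.128 within preparation 2 and -0.121 without WT preparation 1, against 0.211 without WT preparation 2. The Kupffer list in the hepatocyte AICAR interaction turned to 0.016 without WT preparation 2, against -0.299 without WT preparation 1.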

Other observations

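The tests of zinc finger genes and of unnamed probe sets were chosen only after the result was seen; those of starting level and gene length were fixed before.

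Some genes moved in opposite directions with the 2 compounds. In WT hepatocytes Ddit3 rose by 1.28 ± 0.29 with 991 and fell by 1.46 ± 0.29 with AICAR, Nupr1 stood at 1.29 ± 0.08 and -0.62, and the chemokine gene Ccl7 at 0.72 ± 0.07 and -0.74 ± 0.07. In WT MEFs the cholesterol exporter Abca1 was at 0.63 with 991 and -0.86 with AICAR and Zc3h6 at 0.79 and -0.81. AICAR also moved genes in opposite directions in the cell types. In WT the phosphatase regulator Ppp1r10 was at -1.51 in MEFs and 1.14 in hepatocytes. In dKO Pdk4 was at -0.99 and 1.58 and Zfp748 at 0.92 and -2.19. With AICAR in dKO cells 1157 calls were shared by the cell types in the same direction and 607 in opposite directions, against 652.1 and 648.7 for independent calls, while doses differed between them. Every gene named here was called in both comparisons.

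Own hypothesis, starting level: AICAR effects that differ between MEF genotypes may follow from the level before treatment. Across the 2203 interaction genes the correlation with the dKO minus WT level was 0.368, against 0.707 in simulations without any effect, where the shared vehicle arrays alone give it, and 0.052 with the real levels and no interaction. The bound from simulations without any effect, fixed beforehand, was wrong for these genes: it covers all genes and leaves out the real difference in level, with which the shared arrays give only 0.052. Since 0.368 lies between the 0.2 and the 0.5 fixed beforehand, the test cannot tell. Of the 1443 genes higher for WT minus dKO, 853 were higher and 279 lower in dKO before treatment, and of the 760 lower genes 176 were higher and 414 lower.

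Own hypothesis, gene length: a block of transcript elongation could make long genes fall more with AICAR in dKO cells. Instead, above the median level, change and gene span had rank correlations of 0.285 in hepatocytes and 0.185 in MEFs (all genes 0.158 and 0.141). In WT cells they were 0.275 and -0.009. Longer genes did not fall more in dKO, but RNA stability was not measured, so a block is not excluded. In hepatocytes 21% of the shortest genes (median span 4.4 kb) and 4.6% of the longest (105.7 kb) were called lower.

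Own hypothesis, zinc finger genes: genes named Zfp, which encode zinc finger proteins, may fall more often with AICAR in dKO cells than other genes of their level. In hepatocytes 96 of 336 (28.6%) were called lower, against 6.1%, a ratio of 4.71. In MEFs the ratio was 1.39, under the 1.5 needed, and 98 of 336 rose, so the test cannot tell.

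Own hypothesis, unnamed probe sets: the 10092 probe sets without a single gene name may fall with AICAR in dKO hepatocytes because they are dim. At the same level 9.39% of them were lower by at least 1.5-fold, against 0.69% of probe sets that stand for a gene, a ratio of 13.59, which excludes dimness as the whole cause. The other probe sets of named genes fell too (760 of 16752 by 1.5-fold, against 172 of 18193 that stand for a gene), so the falls are not particular to unnamed probe sets. What they measure is not given in the sources used here.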
